A study of Mus musculus with 12 samples.

How the data were processed

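Total RNA from lumbar dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, was sequenced from wild-type mouse pups at postnatal day 9. Pups and dams had been kept from postnatal day 2 to postnatal day 9 either with limited bedding, a protocol that stresses dam and litter, or with control bedding. There were 12 libraries in 4 groups of 3: control females, stress females, control males and stress males. Groups and replicate numbers were taken from the sample labels. The labels do not say which pups shared a litter or whether a library pooled animals, so p-values measure the spread between these samples, which may be smaller than the spread between litters.

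Libraries were made with a directional (strand-keeping) kit, per the labels' protocols. STAR, Salmon, DESeq2 and the mouse build mm10 are named, without versions or roles, in the submitters' processing notes, and the annotation, strand setting and low-count filter are not given in the sources used here. The deposited table gave, for 15322 genes, a normalized signal per library, which the authors scaled in the manner of DESeq2 so that the libraries had like medians, and the mean of the 12 columns. It also gave the authors' log2 fold change of stress over control, its standard error, a test score (the deposited fold change divided by its error), and the deposited p-values with their adjusted values. The sample columns were not whole numbers. In 11 libraries values up to 12 clustered near multiples of a step taken as worth 1 read, and 61.1% to 86.1% of them lay within 0.1 of a step of a multiple. In stress female replicate 2 a step was hardly seen (27.6%), so its depth is uncertain. All are under the 95% needed to recover reads, so no count model was fitted. From the step, depth in the 11 libraries was estimated at 16500000 to 27000000 reads, with a mean of 20100000 ± 2280000 (SD, n = 6) in control and 23000000 ± 3570000 (SD, n = 5) in stress libraries. The share of low values near a multiple was lower in every stress library (27.6% to 65.4%) than in every control library (72.4% to 86.1%), a difference in the values between the treatments that the sources used here do not explain.

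The design written before the data were examined assumed raw counts and a count-based test. Because the unit differed, the stated fallback for normalized values was used. Genes with a normalized count of at least 10 in at least 3 libraries were kept, which left 15194 genes and removed 128. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, in 1 model with a mean for each of the 4 groups and a prior variance that followed mean expression. Fold changes are on that scale, which understates the change of low genes, and are given with their standard errors. The contrasts were stress against control over both sexes, in females and in males, the difference between these effects, and males against females. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The relation of the female and male effects across genes was tested by exact permutation of the treatment labels within each sex.

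A total of 42 gene lists for neuron classes, ion channels, other cell types, hormone response and general processes were fixed before the data were examined. The 13 mitochondrially encoded genes were not among the tested genes, so 41 lists were tested, with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The genes named for each stress contrast were the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM and no predicted name. Up to 4 passing members of each list and the 3 members of lowest p of each called list were added, and Nr3c1, Fkbp5, Tsc22d3, Sgk1, Xist and Ddx3y were always given. Where fewer than 5 genes passed in a direction, those of lowest p were taken, and for the sexes the 6 of lowest p. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here. Coordinates are those of GENCODE M21 on the same build.

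The steps were tested on simulated negative binomial counts drawn from the real gene means for 15194 genes, with a dispersion chosen for the simulation and 200 genes changed by known folds. That dispersion was not estimated from these data, so the shares that follow describe the simulation and need not hold for the real libraries. For both sexes together, 94% of genes changed 2-fold and 78% of those changed 1.5-fold were called, against 6% of those changed 1.2-fold. In females 84% and in males 86% of genes changed 2-fold were called, and 30% and 48% of those changed 1.5-fold. Of the calls for both sexes 4.14% were of unchanged genes, as were 1.83% in females and 7.09% in males, the last above the 5% aimed at, and no gene was called when none was changed. Alternatives covered scaling, filters, sample weights, replicate blocks, the model, the threshold, each library left out and, chosen after the data were seen, the pseudocount, the prior variance, transcript length and GC content (98.4% of tested genes had both), a red blood cell score and a pair of libraries left out together.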

Results

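The series asked which transcripts of immature sensory ganglia differ after early life stress. RNA was measured in lumbar L3 to L5 ganglia of 9-day-old mice raised on limited or control bedding, with 3 libraries for each treatment and sex. Estimated depth ran from 16500000 to 27000000 reads in 11 libraries and was uncertain in stress female replicate 2, and 15194 genes were tested. The sex labels held in all 12 libraries: Xist, the RNA that silences an X chromosome in females, was at 1101 to 1726 normalized counts in females and at most 8.77 in males. Ddx3y, a Y-linked gene, was at 1358 to 1543 in males and at most 1.77 in females. The first principal component, with 24.1% of the variance, placed every stress library above 0 and every control library below 0. It did not follow treatment alone, since within each treatment every male library lay above every female library. Control females were at -19.1 to -15.4 and control males at -11.7 to -7.19. Stress females were at 3.04 to 6.22 and stress males at 15.9 to 26.5.

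Over both sexes, Nppb and Sst fell most among genes with a mean of at least 1 CPM and no predicted name. Nppb, the itch peptide precursor, went from 105 ± 19.1 normalized counts in control to 4.31 ± 1.82 in stress (SD, n = 6 each), a log2 fold change of -4.38 ± 0.27 (SE, limma adjusted p = 2.72e-08). Sst (somatostatin), made in the same neurons, went from 60.6 ± 19.5 to 3.30 ± 2.96, a log2 fold change of -4.10 ± 0.40. Nppb lies on chromosome 4 from 147985788 to 147987205 and Sst on chromosome 16 from 23889573 to 23890958. The irritant-gated channel Trpa1 fell by 1.52 on the log2 scale, from 978 ± 70.7 to 347 ± 75.04 normalized counts, and the nicotinic receptor subunits Chrna6 and Chrnb3 fell by 1.99 and 1.60. The other largest falls were in H2-Aa and Cd74 of antigen presentation, Upp2, Adam8, Calb2 (calretinin, found in mechanoreceptors), Cryba2 and Plbd1, with log2 fold changes from -2.12 to -1.63. The lowest adjusted p, 6.41e-10, was that of Col2a1, a cartilage collagen, which fell by 1.51 from 860 ± 51.0 to 301 ± 21.5.

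Among genes with a mean of at least 1 CPM and no predicted name, the largest rises were in Tunar and the imprinted gene Magel2. Their log2 fold changes were 2.37 ± 0.39 and 2.19 ± 0.22. Magel2 went from 18.6 ± 5.91 to 89.2 ± 26.6 normalized counts. The anion exchanger Slc4a1 of red blood cells rose by 2.13 ± 0.31. Other large rises were in Drd1 (a dopamine receptor), Ipcef1, Hrk (a cell death activator), Mrgpra1, Vip and Prr18, from 1.73 to 1.42. In all, 3984 genes were past the threshold, 1948 higher and 2036 lower (2117 and 1853 with upper quartile scaling). Of the 3984, 613 changed more than 1.5-fold and 191 more than 2-fold. The authors' deposited table listed 4092 genes at an adjusted p under 0.05, and 3871 genes were called in both analyses, each with the same sign. With a red blood cell score as a covariate, chosen after the data were seen, 1675 genes were called. That score was itself higher in stress, so the covariate also removes part of the contrast. Of the genes named for both sexes, Prr18 (1.56, adjusted p = 0.0975), Gfra2 (-0.24, 0.0729), Il31ra (-0.86, 0.192), Scn11a (-0.26, 0.0693) and Rpl10a (0.11, 0.310) lost their call with it, at the log2 fold changes and adjusted p in brackets. So did Nr3c1, Tsc22d3 and Mpo, whose values are given further below. Prr18 also lost its call with 1 prior variance (1.42, limma adjusted p = 0.0521).

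**Figure D1:**
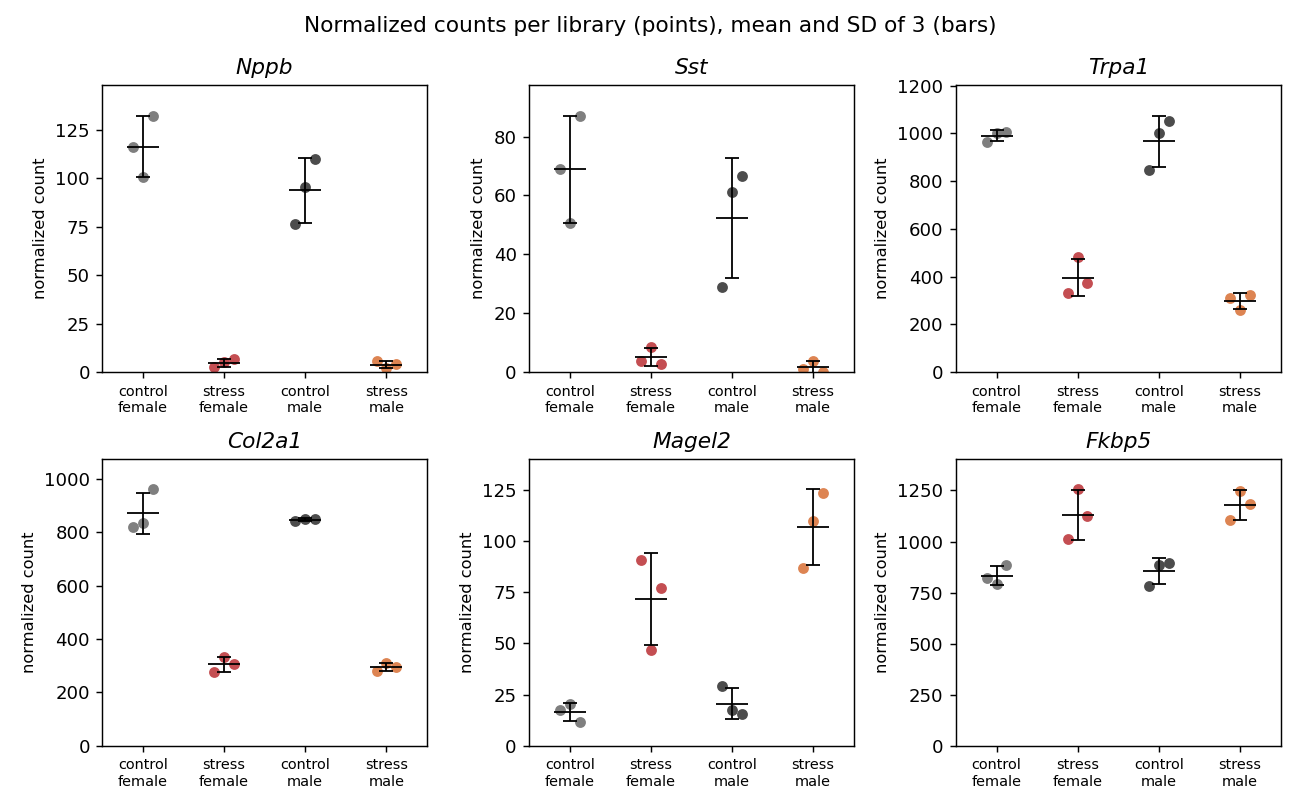
Normalized counts (linear axes) of 6 genes in each library, grouped by treatment and sex, with bars for the mean and SD of 3 libraries. Nppb, Sst, Trpa1 and Col2a1 were lower in stress in both sexes, and Magel2 and Fkbp5 were higher.

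Among neuron classes, the markers of non-peptidergic nociceptors and itch neurons had 16 of 23 members that fell and 2 that rose (16 and 3 adjusted over the list alone; camera adjusted p = 3.28e-06, adjusted p = 0.364 with an estimated correlation). Lpar3 fell by 0.89 and Gfra2 by 0.35, whereas Mrgprx1 rose by 0.74. Of members chosen after their values were seen, Cysltr2 fell by 1.41, Il31ra fell by 1.25, Mrgpra3 rose by 0.62, and Mrgprd was at -0.02 ± 0.05. Markers of A-fibre mechanoreceptors and proprioceptors had 11 of 25 members lower and 4 higher (11 and 4 adjusted over the list alone; adjusted p = 0.00293, adjusted p = 0.531 with an estimated correlation), among them Spp1, which fell by 1.03, and the neurofilament genes Nefh and Nefm, which fell by 0.55 and 0.46. Peptidergic markers had 5 of 18 lower, including Calca and Calcb of the calcitonin gene-related peptide, which fell by 0.48 and 0.76, and 3 higher, and the list was not called by camera (adjusted p = 0.463), though it was by fry (adjusted p = 0.0145). C low-threshold mechanoreceptor, cold-sensing and pan-neuronal lists were not called by camera either, with adjusted p of 0.626, 0.841 and 0.463. Their members went both ways, with 1 of 11 higher and 2 lower, 1 of 6 higher and 1 lower, and 4 of 20 higher and 5 lower.

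Potassium channels had 25 of 53 members lower and 8 higher (25 and 9 adjusted over the list alone; adjusted p = 0.00182, adjusted p = 0.575 with an estimated correlation), with Kcnmb1 at a log2 fold change of -1.20. Sensory transduction channels had 11 of 29 lower and 2 higher (13 and 3 adjusted over the list alone; adjusted p = 0.00357, adjusted p = 0.416 with an estimated correlation), with P2rx6 at -0.94 ± 0.08 besides Trpa1. Sodium channels went both ways: Scn3a, a form abundant before maturity, rose by 1.02 ± 0.09 and Scn11a fell by 0.32, and the list was not called (adjusted p = 0.905). Calcium and HCN channels, transmitter receptors and neurotrophic factors had adjusted p of 0.626, 0.729 and 0.689. Camera tests for a shift in 1 direction, and members of these lists went both ways. Transmitter receptors had 16 of 57 higher and 10 lower, and neurotrophic factors 5 of 22 higher and 4 lower. Calcium and HCN channels had 4 of 22 higher and 2 lower. Of all tested genes 26.2% were called.

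Cell cycle genes had 22 of 30 members higher and none lower (25 adjusted over the list alone; adjusted p = 1.56e-09, adjusted p = 0.364 with an estimated correlation). Aurkb, a mitotic kinase, rose by 0.75 and Top2a by 0.52. Growth and imprinted genes had 11 of 22 higher and 4 lower (13 and 4 adjusted over the list alone; adjusted p = 0.0138, adjusted p = 0.364 with an estimated correlation), with H19 up by 0.86 ± 0.08 and Ndn by 0.41. Nerve injury-induced genes had 8 of 19 higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0173, adjusted p = 0.341 with an estimated correlation); Stmn4 rose by 0.50, and Reg3b went from 0.931 ± 1.498 to 20.1 ± 5.29 normalized counts. Ribosomal protein genes had 12 of 79 higher and none lower (2 and 0 adjusted over the list alone; adjusted p = 0.00137, adjusted p = 0.839 with an estimated correlation), among them Rpl10a at 0.28 ± 0.06, which fell to 0.11 and lost its call with the red blood cell score.

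Respiratory chain genes encoded in the nucleus had 20 of 70 lower and none higher (21 adjusted over the list alone; adjusted p = 0.000351, adjusted p = 0.657 with an estimated correlation), and hypoxia and glycolysis genes had 9 of 23 lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.00756, adjusted p = 0.416 with an estimated correlation). Pkm, a glycolytic enzyme, fell by 0.32. Satellite glia markers had 10 of 20 lower and 1 higher (12 and 2 adjusted over the list alone; adjusted p = 4.26e-05, adjusted p = 0.330 with an estimated correlation), led by Apoe and Ednrb, which fell by 0.74 and 0.65. Collagens and matrix genes had 12 of 28 lower and 3 higher (12 and 4 adjusted over the list alone; adjusted p = 0.0111, adjusted p = 0.817 with an estimated correlation); Lum fell by 1.55 while Tnc rose by 1.06. Fibroblast markers had 6 of 17 lower (6 adjusted over the list alone; adjusted p = 0.0342, adjusted p = 0.817 with an estimated correlation), and myelinating Schwann cell markers had 4 of 20 lower, including Pmp2 at -0.71 ± 0.11 (4 adjusted over the list alone; adjusted p = 0.0221, adjusted p = 0.834 with an estimated correlation). Red blood cell markers had 11 of 16 higher and 1 lower, with a median log2 fold change of 1.11 (the same counts adjusted over the list alone; adjusted p = 0.00134, adjusted p = 0.537 with an estimated correlation). The globin genes among them share reads with near-identical copies, so their single values are uncertain. In all 15 lists were called, and no list was called with an estimated correlation. Of the 15, fry did not call ribosomal proteins (adjusted p = 0.374), myelinating Schwann cell markers (0.358), collagens and matrix (0.0950), respiratory chain genes (0.0804) or fibroblast markers (0.0804). When treatment was reassigned among the libraries of each sex, many other splits also called lists, so the list tests do not by themselves set the real grouping apart.

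**Figure D2:**
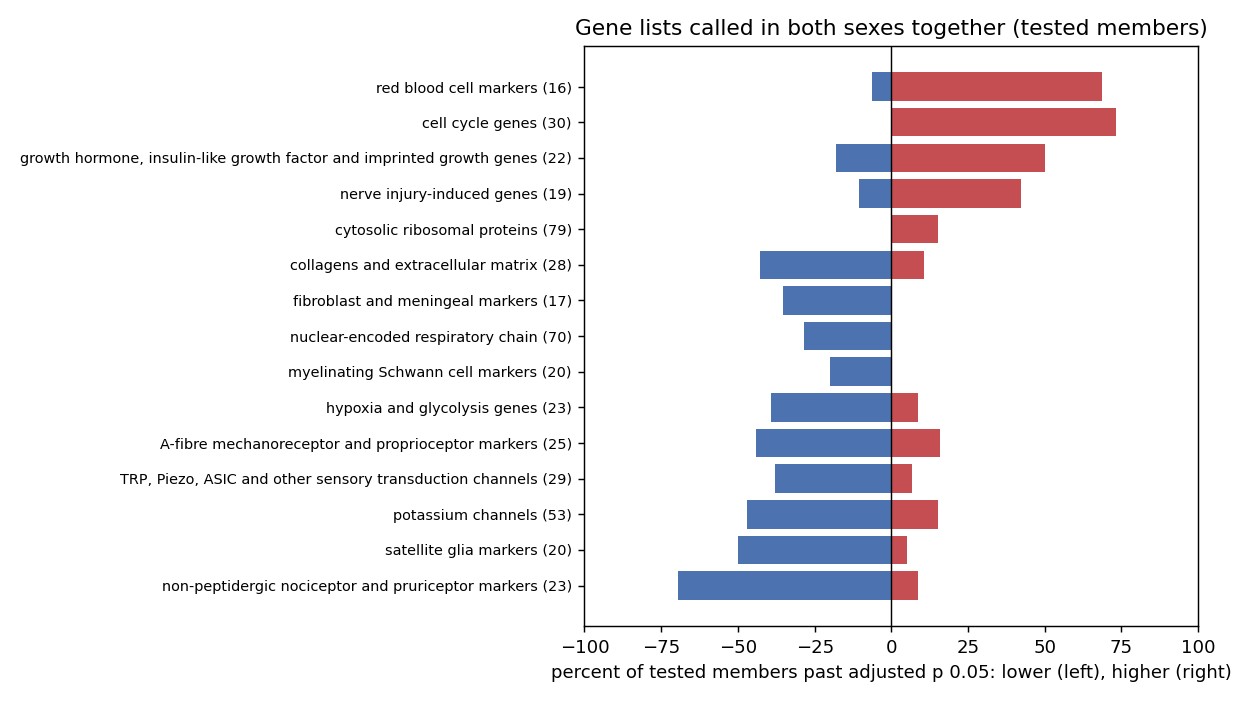
Percent of the tested members of each called list past an adjusted p of 0.05 that were lower (left) or higher (right) in stress over both sexes, with the number tested in brackets. Cell cycle genes had 22 of 30 members higher, and itch and non-peptidergic neuron markers had 16 of 23 lower.

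Genes of the glucocorticoid response were read beside these. Fkbp5, a co-chaperone induced by glucocorticoids, rose by 0.45 ± 0.06, from 844 ± 51.2 to 1155 ± 93.3 normalized counts (SD, n = 6). The receptor genes Nr3c1 and Nr3c2 fell by 0.22 and 0.86. Tsc22d3, another induced gene, fell by 0.21. With the red blood cell score, Nr3c1 and Tsc22d3 were not called (adjusted p = 0.144 and 0.196), each at a log2 fold change of -0.17. Sgk1 was at 0.16 ± 0.07 (limma adjusted p = 0.118). The induced genes as a list had 7 of 28 members higher and 3 lower (7 and 3 adjusted over the list alone) and were not called over both sexes (adjusted p = 0.0651), except with the length and GC trend removed (adjusted p = 0.0402). In males they were called, with 7 members higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.0276, adjusted p = 0.617 with an estimated correlation). The signalling components were not called by camera over both sexes, with 5 of 16 lower and 1 higher (adjusted p = 0.172; fry adjusted p = 0.0183).

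In females 1676 genes were past the threshold, 754 higher and 922 lower (894 and 829 with upper quartile scaling). Nppb was at a log2 fold change of -4.42 ± 0.38, Sst at -3.62 ± 0.56 and Chrna6 at -1.84 ± 0.15. Magel2 rose by 2.04 and Hrk by 1.72. Of genes induced by interferon, Iigp1 went from a mean of 40.8 to 260 normalized counts and Ifi47 from 28.1 to 136. The stress females stood at 555, 85.2 and 139 for Iigp1, so replicate 1 raised that mean; its log2 fold change of 2.25 fell to 1.47 (adjusted p = 0.0157) without that library, and it lost its call with the red blood cell score (1.71, adjusted p = 0.0636). The interferon-stimulated list had 3 of 25 members higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.000353, adjusted p = 0.518 with an estimated correlation). Ifi47 lost its call without stress female replicate 1 (log2 fold change 0.99, adjusted p = 0.115), control female replicate 2 (adjusted p = 0.0996) or control female replicate 3 (adjusted p = 0.0881), with 1 prior variance (adjusted p = 0.0926), and with the red blood cell score (log2 fold change 0.90, adjusted p = 0.253). Fkbp5 rose by 0.44, and Nr3c1 was at -0.22 ± 0.07 (limma adjusted p = 0.0543). Of the lists, 15 were called in females. Itch and non-peptidergic neuron markers had 14 of 23 members lower and 2 higher (17 and 2 adjusted over the list alone; adjusted p = 3.50e-08, adjusted p = 0.261 with an estimated correlation). Cell cycle genes had 8 of 30 higher (12 adjusted over the list alone; adjusted p = 1.97e-08, adjusted p = 0.316 with an estimated correlation). Satellite glia markers had 7 of 20 lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 2.21e-07, adjusted p = 0.116 with an estimated correlation). The number of calls fell to 889 without control female replicate 1, 865 without control female replicate 2 and 891 without stress female replicate 1. It was 915 with the red blood cell score.

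In males 2403 genes were past the threshold, 1171 higher and 1232 lower (1220 and 1191 with upper quartile scaling). Nppb was at -4.34 ± 0.38, Sst at -4.57 ± 0.56 and Chrna6 at -2.14 ± 0.15. Magel2 rose by 2.35 and Drd1 by 1.88, and Fkbp5 rose by 0.46. Zfp967 had the largest fall among genes with a mean of at least 1 CPM and no predicted name, but it was listed at 0 in all 3 stress males and in 2 of 3 control females. It belongs to a family of near-identical zinc finger genes, among which reads can be split, so its value is uncertain. In males 12 lists were called. Itch and non-peptidergic neuron markers had 11 of 23 lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.000373, adjusted p = 0.617 with an estimated correlation), and cell cycle genes had 10 of 30 higher (16 adjusted over the list alone; adjusted p = 1.25e-07, adjusted p = 0.559 with an estimated correlation). Ribosomal protein genes had 15 of 79 higher (16 adjusted over the list alone; adjusted p = 1.86e-09, adjusted p = 0.617 with an estimated correlation). Antigen presentation genes had 4 of 15 lower (4 adjusted over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.329 with an estimated correlation), with H2-Aa at -2.18 ± 0.21. In females 4 of 15 were lower too and 2 were higher, and the list was not called (camera adjusted p = 0.828). The number of calls was 1334 without control male replicate 2 and 986 with the red blood cell score.

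The effects of females and males were correlated across genes. Of the genes called, 466 were higher in both sexes, against 58.1 for independent lists, and 538 were lower in both, against 74.8. The 1 gene that went opposite ways was Zfp967. The effects had the same sign in males for 95.5% of the genes called in females. Across the 15194 genes, which are not independent replicates, Pearson r was 0.450 and Spearman rho 0.533 (exact permutation p = 0.01 for r, two-sided, the smallest the 400 relabellings can give).

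**Figure D3:**
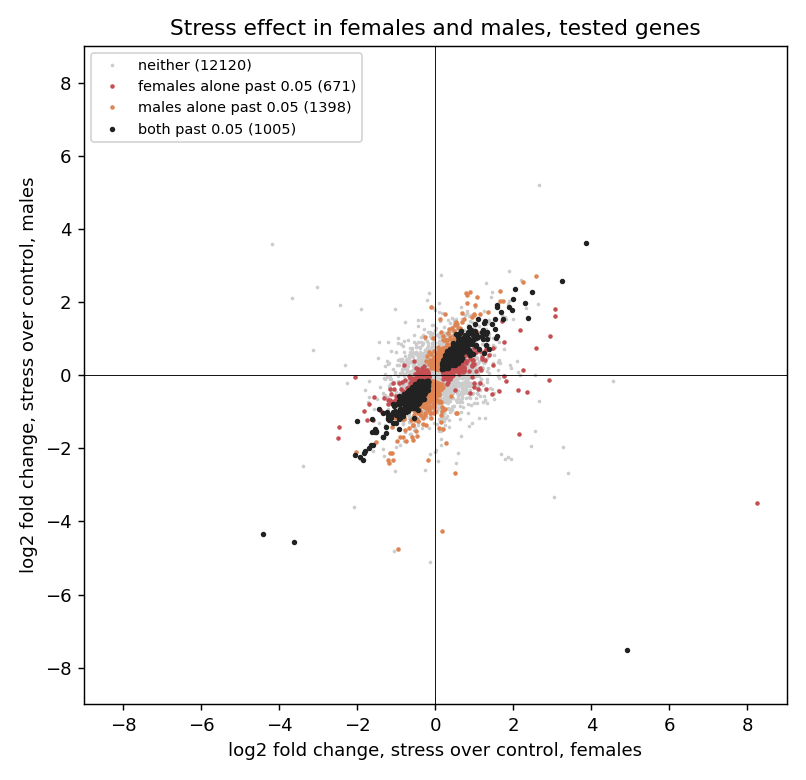
Log2 fold change of stress over control in females (horizontal) and males (vertical) for the tested genes, coloured by the sex or sexes in which the adjusted p was under 0.05. Genes called in both sexes lie along the diagonal, with 1 exception among them.

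No gene passed the threshold for a stress effect that differed between the sexes with limma, and 1260 genes had an unadjusted p under 0.05 where 760 were expected by chance. The gene of lowest p was the uncertain Zfp967 (adjusted p = 0.129), which passed with the replicate block within sex (adjusted p = 0.0127) and with the block across sexes (adjusted p = 0.0327). Among the named falls, Nfxl1 and then H2-Q4 followed, with a male effect minus female effect of -0.97 ± 0.18 and -1.39 ± 0.29 (limma adjusted p of 0.477 and 0.515). Among rises, Eng and Dusp14 were at 0.52 ± 0.12 and 1.08 ± 0.26, each with an adjusted p of 0.515. Leaving out a library gave at most 1 gene, among them Zfp967 without control female replicate 1 (adjusted p = 4.88e-09) and H2-Q4 without control male replicate 3 (adjusted p = 0.0303). Of the lists, 6 were called by camera, and none with an estimated correlation (lowest adjusted p = 0.120): interferon-stimulated genes and antigen presentation were lower in males relative to females, and ribosomal proteins, respiratory chain, collagens and satellite glia markers were higher. Over genes, this contrast had a Spearman rho of 0.282 with GC content. With the length and GC trend removed, respiratory chain genes (adjusted p = 0.748, the median going from 0.058 to 0.020) and satellite glia markers (adjusted p = 0.0531) lost their call. The interferon (median -0.64), antigen presentation (-0.68), ribosomal protein (0.16) and collagen (0.14) lists kept it, and non-myelinating Schwann cell markers gained one (adjusted p = 0.0274). Isg15, a ubiquitin-like interferon response gene, averaged 31.3 normalized counts in control females, 119 in stress females (202, 39.95 and 115 in replicates 1 to 3), 32.4 in control males and 25.1 in stress males. Its male effect minus female effect was -2.07 (adjusted p = 0.515) and -1.55 without stress female replicate 1. Of the antigen presentation list, Tap1, Psmb8 and H2-K1 also varied widely among stress females, at 475 ± 304, 241 ± 143 and 1037 ± 310 normalized counts (SD, n = 3). H2-Q4 varied less (298 ± 56.9). Whether single libraries drive the difference of that list was not tested.

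**Figure D4:**
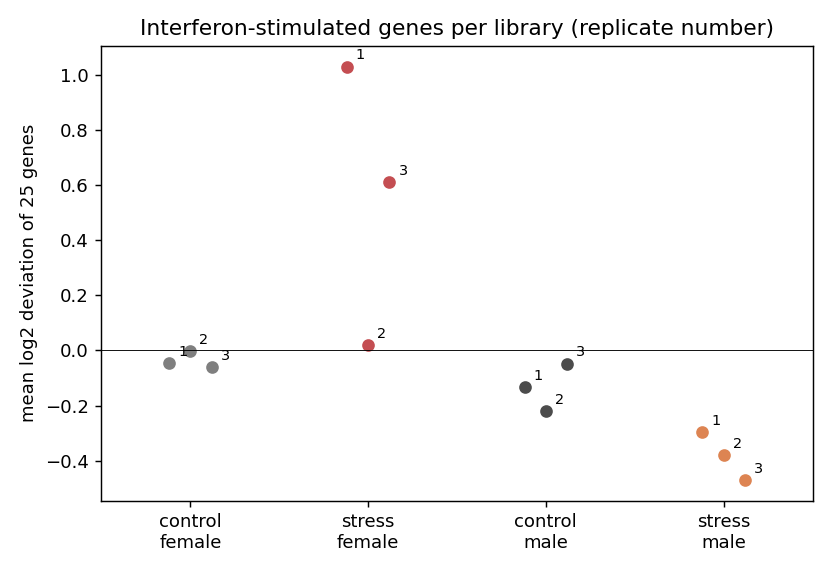
Mean log2 deviation of the 25 tested interferon-stimulated genes from their mean over all libraries, for each library, numbered by replicate. Stress females 1 and 3 stood at 1.03 and 0.61, stress female 2 at 0.02, and the stress males between -0.47 and -0.30.

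Between males and females over both treatments, 15 genes were called, 6 higher in males and 9 higher in females. Those of lowest p were the Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d, at log2 fold changes of 9.65, 8.49, 8.55 and 7.60, and the X-linked Xist and Eif2s3x, at -9.08 and -0.64. The number was 30 without stress female replicate 2 and 27 without stress male replicate 1.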

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

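The tests of single-animal activation and of macrophage number were chosen after the result was seen. The 6 lists named for the sexes stood out because camera called the difference between the male and the female stress effect; with an estimated correlation none was called (lowest adjusted p = 0.120). The median of that difference, males minus females on the log2 scale, was -0.72 for interferon-stimulated genes, -0.62 for antigen presentation, 0.25 for ribosomal proteins, 0.15 for collagens and matrix, 0.12 for satellite glia markers and 0.058 for respiratory chain genes. For the last of these it was 0.020 with the length and GC trend removed, and neither that list (adjusted p = 0.748) nor the satellite glia markers (adjusted p = 0.0531) were then called. The other 4 lists stayed called, with medians of -0.64 for interferon-stimulated genes, -0.68 for antigen presentation, 0.16 for ribosomal proteins and 0.14 for collagens and matrix. Among 100 splits of the libraries, 85 called at least 6 lists (at most 23), so chance cannot be excluded for this number.

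For the interferon genes, the range of the per-library score among the 3 stress females was 5.83 times the widest range in any other group. Stress females 1 and 3 were high and stress female 2 was not, so activation in single animals, such as an infection of a pup or litter, is a candidate explanation for the rise in females. It would not give the lower scores of stress males (-0.47 to -0.30) beside control males (-0.22 to -0.05), where the median fold change of the list was -0.22 (3 members fell and none rose, adjusted p = 0.0541). The median difference of the macrophage list was -0.019, short of the -0.358 or beyond written as the bound for more macrophages. That shortfall exceeded the spread between macrophage genes (0.22), a rule that was not part of the written test. The bound written against more macrophages was not met either. The median had the same sign as that of the interferon list. The macrophage score was also higher by 0.126 in stress females 1 and 3 than in stress female 2, through replicate 3 (0.288, against 0.027 and 0.032 in replicates 1 and 2). The test therefore does not decide whether macrophage number played a part. For the difference between the sexes, the interferon list had a camera adjusted p of 9.48e-12. It was 0.684 with an estimated correlation and 0.513 with fry. A sex-dependent response to stress stays open, since the labels do not give litters and it cannot be separated from them.

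For the counts of genes, 1 of 100 splits, the real one, gave 3984 genes for stress over both sexes (highest other 303). This argues against chance only if the libraries are independent. The labels do not give litters, and a split mixes litters, so a difference between a few litters is not excluded. For the 15 genes between males and females, too, the real split alone gave as many (1 of 100, highest other 8). For the difference between the sexes the real count was 0, so all 100 splits gave as many; the highest other was 3984, the split that exchanges the treatments in 1 sex. The 10 splits within a sex are too few for a share under 0.05: females had 1676 genes against at most 1 in another split, and males 2403 against at most 2. For lists over both sexes, 14 of 100 splits called at least 15 (highest other 20), so chance cannot be excluded. Within females 15 lists were called against at most 11 in another split, and within males 12 against 21, again with only 10 splits; in males 5 splits gave as many.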

How the results depend on the processing

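The pseudocount, prior variance, length and GC, red blood cell and paired-library settings were chosen after the data were seen. The planned count-based tests (quasi-likelihood with TMM, DESeq2 and voom) were not run, because whole reads were not recovered; the RLE scaling leaves these values as they are and tests nothing. Over the other settings, genes changed by stress in both sexes stayed between 3155 and 4466, except at an adjusted p under 0.1 (5105) and with the red blood cell score (1675, with 915 in females and 986 in males); the score rises with stress, which removes part of the contrast. Over 94 results for single genes and their 2589 alternatives, 2560 were on the same side, 15 lost their call and 11 gained one. These counts include the RLE scaling (94 the same by construction) and the adjusted p under 0.1, which cannot remove a call. Many of the genes were named for large changes, so the counts say little about genes nearer the threshold. The red blood cell score took most of the lost calls. Nr3c1 in females, just short of the threshold, passed 0.05 in 6 settings. Mrgprd, near 0, changed sign with that score (0.093) and ran from -0.064 to 0.0083 without each library. Upper quartile scaling shifted the median of all genes by 0.011 and turned the balance of calls towards higher ones over both sexes, in females and in males. Leaving out each library gave 3155 to 3959 genes for both sexes, 865 to 1951 in females, 1334 to 2630 in males, 0 to 1 for the sex difference and 11 to 30 between the sexes; 1 library fewer also weakens the test. An adjusted p under 0.1 gave 2571 genes in females. Leaving out both stress libraries numbered 2 gave 1 gene for the sex difference, 32 between the sexes and 19 lists in males; the cause was not tested. Sample weights called 20 lists in males. The correlation of the sexes ran from 0.393 to 0.628.

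The replicate numbers did not pair the samples: the correlation of deviations ran from -0.07 to 0.21, with 3 of 6 pairs over 0.1, and 5 of 12 libraries correlated best with their own number. With the replicate block within sex 4133, 1840, 2607, 2 and 18 genes were called (both, females, males, difference, sexes; Zfp967 and Gm14440 for the difference), and with the block across sexes 4176, 1880, 2617, 1 (Zfp967) and 17. Lists depended most on the correlation between genes: an estimated one called 0 in each contrast, and fry 16, 9, 9 and 0 (both, females, males, difference). Lists without each library ranged from 13 to 19 (both), 14 to 20 (females), 10 to 18 (males) and 4 to 9 (difference).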

Other observations

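The tests of the share of non-neuronal cells, and the liver pattern itself, were chosen after the values were seen. Clock genes had 6 of 18 members higher and 5 lower, with Dbp at -0.61 ± 0.09, where 26.2% of all tested genes were called. A test for a shift in 1 direction, such as camera, can miss a list whose members go both ways. Cholesterol synthesis genes had 6 of 23 lower and 1 higher, with Lss at 0.45 ± 0.07. Cartilage and bone markers had 7 of 16 lower and 3 higher, and adipocyte markers had 2 of 9 higher and 1 lower, with Cidea at 1.07 ± 0.13. Macrophage markers had 2 of 20 higher, endothelial markers 1 of 16 higher and 2 lower, and pericyte markers 4 of 13 lower. Non-myelinating Schwann cell markers had 3 of 11 higher. Skeletal muscle markers had 1 of 20 higher. Immediate early genes had 1 of 22 higher and 1 lower, and cytokines 1 of 13 higher and 2 lower. Leukocyte markers had 1 of 14 higher, Mpo, at 1.74 ± 1.71 normalized counts in control and 17.2 ± 7.80 in stress; it lost its call with the red blood cell score (log2 fold change 2.25, adjusted p = 0.0657). Central nervous system markers had 2 of 9 higher, with Agt at 0.86 ± 0.12. Interferon-stimulated genes had 1 of 25 higher and 2 lower, and antigen presentation genes 4 of 15 lower, all of class II (H2-Aa, H2-Ab1, H2-Eb1 and Cd74). None of these lists was called by camera over both sexes. By fry, cartilage and bone (adjusted p = 0.000324), antigen presentation (adjusted p = 0.00459), adipocyte (adjusted p = 0.0125) and pericyte (adjusted p = 0.0349) markers were. With the length and GC trend removed camera also called pericyte markers (adjusted p = 0.0402).

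Over both sexes, camera called the cell cycle and growth lists as higher, and the itch neuron, A-fibre, satellite glia and respiratory chain lists as lower, but none of these with an estimated correlation (adjusted p of 0.330 to 0.657). These were 6 of the 15 lists called, and among the neuron lists the peptidergic and pan-neuronal ones were not called by camera. Delayed postnatal maturation may account for part of the pattern. A further list of genes known to fall after birth and another of genes known to rise were written before their values were seen, with no member in the fixed lists. The median log2 fold change was 0.18 over 25 falling genes (12 rose, 1 fell) and -0.24 over 21 rising genes (3 rose, 12 fell), a difference of 0.418. It lay above all of 10000 random pairs of lists matched on expression (at most 0.278), though these do not keep the correlation between genes of a list. The exact permutation p of the library scores within sex was 0.005, the smallest the 400 relabellings can give. With an estimated correlation, unadjusted camera p was 0.0373 for the falling and 0.0334 for the rising list. It was 0.0764 and 0.00970 in females, and 0.0310 and 0.174 in males. In males the preset correlation gave 0.124 for the rising list (3 rose, 7 fell). An earlier draft of the rising list gave a difference of medians of 0.371. Dcx and Nnat rose by 0.92 and 0.87, but Ndrg2, on the rising list, also rose, by 0.44, and Mdk, on the falling list, fell by 0.41.

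Bias by transcript length or GC content was argued against for the cell cycle and itch neuron lists: with each library's trend on both removed, the median of the cell cycle list was 0.379, where it had been 0.379 before. That of the itch and non-peptidergic list went from -0.354 to -0.343. Both stayed called over both sexes, as did the A-fibre (adjusted p = 0.000700), satellite glia (adjusted p = 4.42e-05) and respiratory chain (adjusted p = 0.00124) lists. For the difference between the sexes, no bound was written in advance; the interferon, antigen presentation, ribosomal protein and collagen lists stayed called, and the respiratory chain and satellite glia lists did not. An equal fall of all non-neuronal cells would move their markers alike. The macrophage score minus the satellite glia score was higher in stress by 0.399 (exact permutation p = 0.00216, n = 6 each, SD of controls 0.0997). The direction of both lists had already been seen, so this argues only against such an equal fall. A lower share of satellite glia, myelinating Schwann cells or fibroblasts, whose markers camera called lower, stays open. With the red blood cell score as a covariate, 14 lists were called over both sexes and the median of the cell cycle list was 0.269 (5 members rose); since the score rises with stress, red blood cell content stays open. Body size, litter and the time of dissection were not tested and remain open, as does the difference in low values between the treatments.

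In stress male replicate 2, 18 liver transcripts, first seen in the values, were under 1 normalized count while every other library held them; Serpina6, for instance, was at 83.0 to 228 in the others. If these were reads of liver origin, more than 50% of a further list of liver genes written before their values were seen would be under 2 in that library and above 2 in the rest. In all 7 of the 31 in the table were (22.6%, below the 25% set in advance as too few), which argues against liver reads as the sole source. Alb, picked after its value was seen, was at 7.79 against 996 to 2667 in the others, while Ttr, also abundant in liver, was at 43.0 against 21.6 to 57.8, so the source stays open. Liver genes made up 0.125% of the genes called in males (3 of 2403). Genes near 0 in a single stress male spread widely within that group and are hardly called, so this low share decides little. Without that library 1680 genes were still called, so the male calls did not arise from it alone. How far that library shaped the other calls stays open.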
